A study of Mus musculus with 2 samples.

How the data were processed

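RNA of mouse CD4+ T cells was sequenced by the authors. Per the labels' protocols, naive CD4+ T cells were cultured for 72 h with anti-CD3ε (0.25 µg/mL), anti-CD28 (1 µg/mL), TGF-β (0.1 ng/mL) and IL-6 (20 ng/mL), and libraries were made from ribosome-depleted RNA with the KAPA Hyper Prep kit and sequenced on an Illumina HiSeq instrument. The samples analysed here are 2 libraries of Malat1 knockout Th17 cells, grouped by their titles and described by the submitters as independent biological replicates. The characteristics label of replicate 2 names Malat2 where its title names Malat1, and the title was followed. The wild-type libraries set against them belong to another series, per the series' design text. Genotype and series are therefore the same split, and no batch can be told apart from genotype.

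A single deposited table of 16385 genes was used. Its raw counts are whole numbers of reads per gene, deposited by the authors for each library. Its normalized counts, a signal that is never negative, were made by the authors by dividing the counts by a size factor per library, and its column of means is the authors' average of that signal over the 4 libraries of their fit. The log2 fold changes, knockout over wild type, and their standard errors are on the log2 scale and were deposited by the authors. The Wald statistic is a score the authors deposited, equal to the log2 fold change over its standard error. The p-values and adjusted p-values were deposited by the authors, who ran DESeq2 1.18.1 per the submitters' processing notes. STAR 2.6.1a, featureCounts and the genome build mm10 are named in the submitters' processing notes. The gene annotation, the treatment of multi-mapped reads, the strand setting and the factors of the authors' model are not given in the sources used here, although the name of the table speaks of several factors. The table holds 4 further columns of per-sample values, for wild-type libraries, which match no sample here and were not used. They were displayed when the table was opened, and 1 of these libraries was then seen to stand apart, before the near-absent genes were defined and the tests on them chosen.

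No new test between genotypes was run, since the wild-type libraries are not among the samples analysed here. A gene was counted as higher or lower where the authors' adjusted p was under 0.05. DESeq2 gave an adjusted p to 14481 genes and none to 1904, which stayed without one. The sign of the fold change matched the side of the mean of all libraries on which the knockout mean lay for 97.8% of genes, and the fold change was read as knockout over wild type. The wild-type mean was not read from the table: it is the value implied by the mean over 4 libraries and both knockout values, and is called the implied wild-type mean. In the 7043 genes with a mean of 500 or more that were not near-absent, the log2 ratio of knockout to implied wild-type mean lay a median of 0.0015 from the authors' fold change. Near-absent genes were defined, after the data were seen, as those with an implied wild-type mean of 100 or more and a knockout mean under 2% of it.

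The groups, the tests, the gene lists, the rule for named genes and most alternatives were set before the data were examined. The genes named are Malat1 and, among genes with an adjusted p under 0.05 and a mean normalized count of at least 50, the 12 with the highest and the 12 with the lowest fold change, leaving out predicted and sex-linked genes. To these were added at most 4 members of each list with the smallest adjusted p, ties broken by the p-value, and T helper genes fixed by name, among them Rora, Il17a, Il17f, Il21, Il22, Il23r, Ccr6, Ahr, Maf, Il10, Foxp3, Tbx21, Ifng, Gata3, Bcl6, Il2 and Neat1. Any other gene was named after its values were seen. Malat1 and Neat1 are not analysed here.

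The 32 lists covered Th17, Th1, Th2, Treg and Tfh lineage genes, naive and central memory T cell genes, T cell activation and inhibitory receptors, T cell cytokines and chemokines, TGF-β signalling, the IL-6 and STAT3 response, the interferon response, cholesterol biosynthesis, glycolysis and hypoxia, and oxidative phosphorylation. They also covered S phase, G2 and M phase, replication-dependent histones, SR proteins and nuclear speckles, neighbours of Malat1, ribosomal proteins, mitochondrially encoded genes, short structured RNAs, heat shock and immediate early genes, the integrated stress and unfolded protein response, p53 and apoptosis, sex-linked genes, and markers of CD8 T cells, NK and gamma-delta T cells, B cells, myeloid cells, dendritic cells with MHC class II, and erythroid cells with platelets. The ribosomal protein list left out S6 kinases, Rps19bp1, pseudogenes and genes named as like genes. The 29 lists with 5 or more measured members were tested with limma 3.58.1 (cameraPR, two-sided, preset inter-gene correlation of 0.01) on the authors' Wald statistic in R 4.3.3, with Benjamini-Hochberg adjustment over the lists. The test is competitive, which means that it compares the statistics of a list with those of all other genes. A list that tested higher or lower did so relative to those genes. An estimated correlation needs the libraries of both genotypes and cannot be had here, so larger preset correlations of 0.05 and 0.1 were tried. The list test was tested on simulated data by shuffling the statistic over 16380 genes 100 times: 0.05 lists passed per shuffle, and a list of 31 genes shifted by 1 SD was recovered in 97% of shuffles. Shuffling removes correlation between genes, so these shares do not show whether a preset correlation of 0.01 is large enough for the real data.

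Gene names and positions were matched by identifier to GENCODE M21 on GRCm38, the assembly that mm10 names, and 97.3% of identifiers carried the same version. Names of 26 genes that a spreadsheet had turned into dates were restored from their identifiers, and for 5 symbols found on 2 rows the row with the higher mean was used in the lists. GC content was taken from the longest transcript of each gene, and its trend was the median fold change in 20 bins of genes with a mean of 500 or more. The trend was interpolated between bins and held flat beyond the outermost ones. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

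The totals were 21554852 and 26916169 counts. A floor of 3 counts corresponded to a normalized count of 2.90 in replicate 1 and 2.28 in replicate 2. Shares of counts carry 95% Wilson intervals and ratios of near-absent genes exact Poisson intervals, and both cover counting error only, since the reads carry no molecular identifiers in the sources used here. The alternatives were adjusted p thresholds of 0.01 and 0.1, minimum fold changes of 1.5 and 2, Benjamini-Hochberg adjustment over every gene, minimum means of 50 and 10, leaving out predicted genes, centring on the median, a rank-based list test, the log2 fold change as list statistic, scaling to genes other than the 20 most abundant, and a window of 5 Mb around Malat1. Subtracting the GC trend and leaving out near-absent genes, also with the fold change as list statistic, were added after the data were seen.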

Results

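Malat1 is an abundant nuclear long non-coding RNA, and the study asked which transcripts differ in its absence in Th17 cells, the helper T cells that secrete IL-17. RNA was sequenced from mouse T cells lacking Malat1 after 72 h under Th17 conditions, in 1 group of 2 biological replicates. The libraries held 21554852 counts (replicate 1) and 26916169 counts (replicate 2), over 14269 and 14493 genes with at least 1 count. Malat1 itself is not analysed here, so the genotype of the libraries rests on their titles. The label of replicate 2 that names Malat2 could not be checked for the same reason.

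The knockout cells carried the transcripts that define Th17 cells at high levels. Il17f, encoding IL-17F, ranked 13 among all genes in the knockout mean, with a normalized count of 61867 ± 2341 (SD, n = 2), and Il17a, encoding IL-17A, ranked 47 with 27413 ± 1722 (SD, n = 2). Il22 stood at 8876 ± 1367, Rora, which encodes a nuclear receptor of the lineage, at 5055 ± 545, and Il21 at 4033 ± 350 (SD, n = 2 for each). Among transcription factors, Maf and Ahr of the Th17 list stood at 1041 ± 2.75 and 759 ± 53.3, and Gata3, Tbx21 and Bcl6 of other helper lineages at 643 ± 49.7, 401 ± 14.5 and 299 ± 34.2 (SD, n = 2 for each). Other members of those lineages' lists were abundant, such as Il4ra at 15457 ± 1627 and Icos at 12998 ± 1395 (SD, n = 2 for each). Ifng had 14 counts in each library. Foxp3, the regulator of Treg cells, had 0 counts in replicate 1, which allows up to 2.90 normalized counts, and 4 counts in replicate 2. Among these genes above the floor, Il2 differed most between the replicates, with normalized counts of 1615 and 3247.

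**Figure D1:**
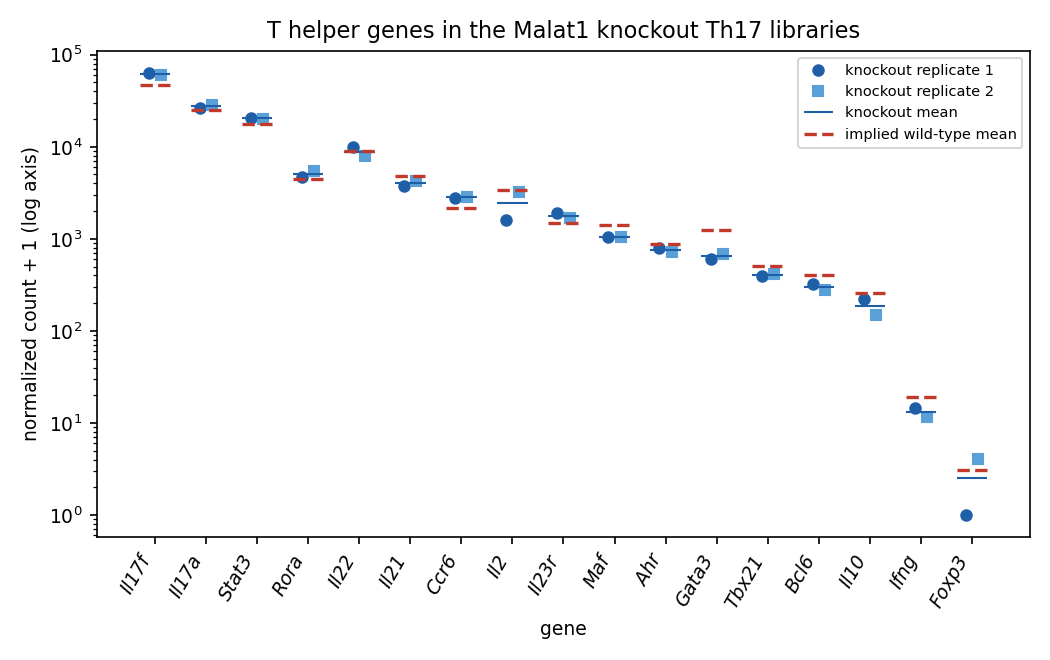
Normalized counts plus 1 (log axis) of T helper genes in both Malat1 knockout Th17 libraries (points), with the mean of the knockout libraries (solid line) and the implied wild-type mean (dashed line). Il17f and Il17a lie highest, with knockout means of 61867 and 27413, and Foxp3 lies lowest.

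Across genes, the knockout libraries had a Pearson correlation of 0.993 (log2 of the normalized count plus 1) and a Spearman correlation of 0.993, where genes are not independent replicates. In the 10540 genes with a knockout mean of 50 or more, the median absolute log2 ratio between the libraries was 0.10, and 16 genes differed by over 2-fold. Mitochondrially encoded transcripts took 0.859% of the counts (95% Wilson interval 0.855 to 0.863) in replicate 1 and 1.175% (1.171 to 1.179) in replicate 2. The 20 most abundant genes took 8.35% and 7.80%.

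The comparison of knockout with wild-type Th17 cells asked which genes depend on Malat1. Il17f was the 1 gene that rose: the authors' deposited table gives it a log2 fold change, knockout over wild type, of 0.40 (SE 0.081), a 1.32-fold higher level, with an adjusted p of 0.00124 (the authors' DESeq2 Wald test, Benjamini-Hochberg). It lies on chromosome 1 from 20777146 to 20790617 (GRCm38, ENSMUSG00000041872.9), and its normalized counts in the knockout libraries were 63523 and 60211. The implied wild-type mean was 46851. A further 22 genes fell, among them 6 mitochondrially encoded transcripts, 12 near-absent genes, and Marcks, Myh10 and Ddx3x, which lie outside the naming rule and were named after their values were seen. By the authors' deposited table, 23 genes thus passed an adjusted p of 0.05 among 14481 genes with one (the authors' DESeq2).

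The 6 mitochondrially encoded transcripts that fell encode subunits of the respiratory chain. In the authors' deposited table, mt-Nd5 fell by 0.64 (SE 0.074, adjusted p 6.37e-14), mt-Cytb by 0.64 (SE 0.13, adjusted p 0.000687), mt-Nd2 by 0.57 (SE 0.11, adjusted p 0.000671) and mt-Co1 by 0.33 (SE 0.064, adjusted p 0.000648) on the log2 scale (the authors' DESeq2). The same source, the authors' deposited table, gives log2 fold changes of -0.70 for mt-Nd4 and -0.43 for mt-Nd1, with adjusted p of 0.00455 and 0.00132 (the authors' DESeq2), and these genes were named after their values were seen. The same 6 transcripts also differed between the knockout libraries, by a median of 0.52 on the log2 scale (range 0.30 to 0.65), higher in replicate 2. Their GC content was low, with a median of 37.4%, and fold changes of all genes followed GC content. Once the GC trend was subtracted from the authors' deposited table, mt-Nd5, mt-Cytb and mt-Nd2 kept an adjusted p under 0.05, while mt-Nd4 (0.101), mt-Nd1 (0.204) and mt-Co1 (0.204) did not, by adjusted p recomputed from the authors' DESeq2 standard errors. Their log2 fold changes were then -0.58, -0.31 and -0.23.

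Marcks encodes a membrane-bound substrate of protein kinase C, Myh10 a non-muscle myosin heavy chain and Ddx3x an RNA helicase. In the authors' deposited table the log2 fold change of Marcks was -1.63 (SE 0.33, adjusted p 0.00128), that of Myh10 -0.70 (SE 0.17, adjusted p 0.0282) and that of Ddx3x -0.46 (SE 0.090, adjusted p 0.000671), all by the authors' DESeq2. All 3 were well expressed in the knockout libraries, at normalized counts of 770 ± 207 for Marcks, 1527 ± 173 for Myh10 and 8291 ± 1155 for Ddx3x (SD, n = 2). Expression in knockout does not exclude an added source of their RNA in the wild-type libraries, such as foreign cells. That was not tested for these 3 genes.

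The largest falls were in genes that the knockout libraries barely contained. Fhl1 (a LIM domain protein), Ghr (the growth hormone receptor), Pcdh10 (a protocadherin) and Actg2 (smooth muscle actin) had log2 fold changes of -7.90, -7.45, -7.18 and -6.97 in the authors' deposited table, with adjusted p of 1.18e-05, 0.00219, 8.07e-07 and 0.00223 (the authors' DESeq2). Hoxa11, Hgd, Igdcc3, Nfib, Ggt1, Cgnl1, Slc3a1 and Acy3 made up the rest, from -6.95 to -5.56 in the authors' deposited table. Counts of these 12 genes in both knockout libraries together ran from 1 to 17. The implied wild-type mean of Fhl1 exceeded the knockout level 654-fold (95% exact Poisson interval of the knockout counts 181 to 5402), and that of Acy3 89.3-fold (55.8 to 153), intervals that take the implied mean as fixed. The folds fitted in the authors' deposited table are smaller, 239 for Fhl1 and 47.2 for Acy3 (the authors' DESeq2). These 12 are part of 235 near-absent genes, of which 131 had 0 counts in both knockout libraries and 223 did not pass the authors' test. The near-absent genes with the largest implied wild-type means, looked up after the data were seen, were Gpx3 (12860), Kap (11576) and Sparc (5956), whose knockout means were 20.1, 1.62 and 1.52. In the authors' deposited table none of the 3 passed, with unadjusted p of 0.0389, 0.212 and 0.0220 (the authors' DESeq2 Wald test).

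**Figure D2:**
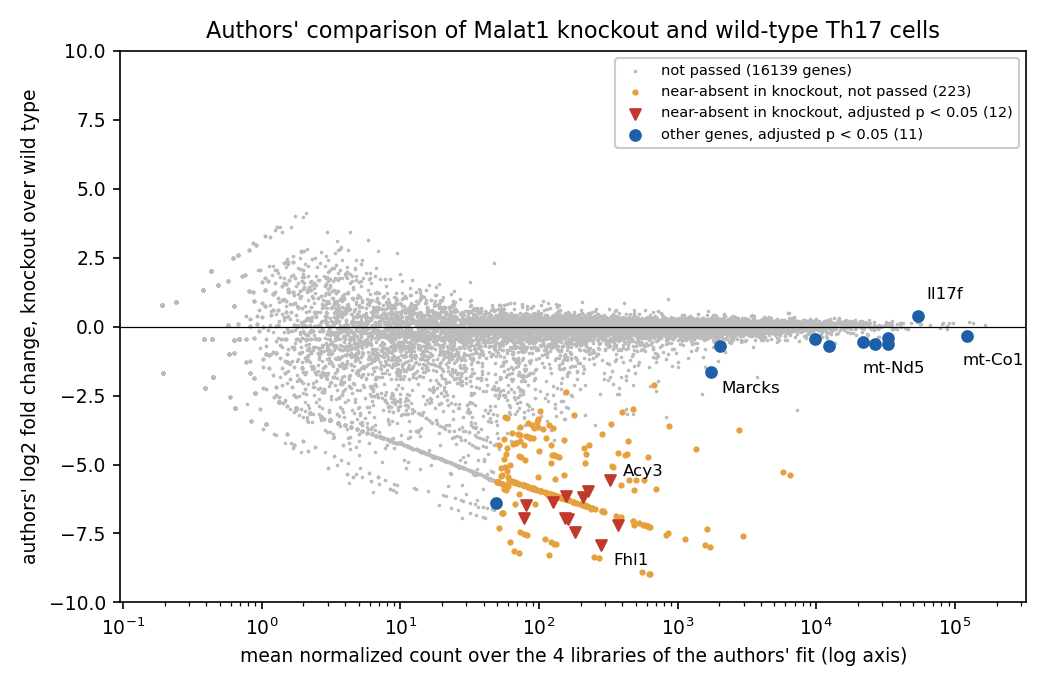
Log2 fold change of knockout over wild type in the authors' deposited table against the mean normalized count over the 4 libraries of the authors' fit (log axis), 1 point per gene. Near-absent genes are drawn as orange points where they did not pass (223) and as red triangles where they did (12), and the 11 other genes with an adjusted p under 0.05 in blue, with Il17f the 1 point above 0 among the genes that passed.

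At an unadjusted p under 0.05, 64 genes were higher and 282 lower in the authors' deposited table (the authors' DESeq2 Wald test). Evenly spread p-values would give 819 among 16385 genes. The SD of the Wald statistic was 0.71 over all genes and 0.76 at means of 50 or more, narrower than the test assumes. The test was thus conservative, and genes that did not pass are not shown to be unchanged. Leaving out the near-absent genes left 11 of the 23 genes, and because the wild-type libraries come from another series, genotype and series cannot be told apart in any of them.

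Th17 lineage genes other than Il17f did not pass singly. Of 27 measured, 1 rose, 0 fell and 26 did not pass, and adjusted over the list alone the count was also 1, again Il17f. In the authors' deposited table the log2 fold changes of Ccr6 (0.40, SE 0.18), Stat3 (0.22, SE 0.088), Il23r (0.28, SE 0.20), Rora (0.17, SE 0.13) and Il17a (0.15, SE 0.14) lay above 0. Those of Il22 (0.0028, SE 0.14), Il21 (-0.21, SE 0.25), Ahr (-0.20, SE 0.28) and Maf (-0.42, SE 0.27) lay near or below it in the authors' deposited table. As a list, Th17 genes tested higher relative to other genes, with a median log2 fold change of 0.11 and an adjusted p of 0.00133 (limma cameraPR). The 18 pan T cell genes had a median of 0.11 too. The call of the Th17 list was lost in the rank-based test (adjusted p 0.123) and with a preset correlation of 0.1 (0.148).

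Among the other helper T cell lists, 0 genes passed over all genes by the authors' DESeq2. The Th1 list of 19 genes had 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone, with Lta at 0.34 (SE 0.20) and Gzmb at -0.47 (SE 0.31) in the authors' deposited table, and Tbx21 at -0.35 and Ifng at -0.48. Of 13 Th2 genes, 2 passed adjusted over the list alone, and the authors' deposited table puts Il4ra at 0.23 (SE 0.084) and Epas1 at -1.09 (SE 0.38), while Gata3 at -0.80 (SE 0.48) did not pass. The 20 Treg genes gave 1 higher gene at an unadjusted p under 0.05 (Capg, 0.25 in the authors' deposited table) and 0 adjusted over the list alone, with Foxp3 at the floor and Il10 at -0.44 (SE 0.50). The 13 Tfh genes gave 1 likewise (Icos, 0.23 in the authors' deposited table) and 0 adjusted over the list alone, with Bcl6 at -0.39 (SE 0.50). Th1 genes (adjusted p 0.0369) and Treg genes (0.0164) tested higher as lists, and Th2 genes (0.593) and Tfh genes (0.693) did not pass (limma cameraPR). Both calls were lost with a preset correlation of 0.05 (Th1 0.128, Treg 0.0832), that of Treg genes also in the rank-based test (0.0935) and that of Th1 genes with a minimum mean of 50 (0.0506).

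Ccr7, a homing receptor of naive T cells, was the 1 of 18 naive and central memory genes that passed adjusted over the list alone, at 0.28 (SE 0.090) in the authors' deposited table, while 0 passed over all genes and Actn1 stood at -0.75 (SE 0.32). The 23 activation and inhibitory receptor genes gave 0 over all genes by the authors' DESeq2 and 0 adjusted over the list alone. At an unadjusted p under 0.05, Icos (0.23), Tnfrsf9 (0.23), Cd5 (0.18) and Cd6 (0.17) were higher in the authors' deposited table. Of 35 cytokine and chemokine genes, Il17f alone passed, over all genes and adjusted over the list alone, and Il2 stood at -0.52 (SE 0.76) in the authors' deposited table. The naive (adjusted p 0.0302) and activation lists (0.00493) tested higher and the cytokine list did not pass (0.282, limma cameraPR). Both calls were lost in the rank-based test (naive 0.123, activation 0.223) and with a preset correlation of 0.05 (0.110 and 0.0506), and that of the naive list with a minimum mean of 50 (0.0506). For the activation list the median (-0.0062) and mean (-0.030) log2 fold change lay below 0, although its test pointed higher. The test compares Wald statistics, with a mean of 0.37 in this list, with those of other genes, so the signs need not match. The mean log2 fold changes of the Treg (-0.0061), naive (-0.060) and IL-6 and STAT3 (-0.058) lists lay below 0 too, with medians above 0. Among lists that did not pass, the tests of the Tfh, cytokine, G2 and M phase and dendritic cell lists pointed higher with means of -0.11, -0.28, -0.017 and -0.32, and that of the p53 list did so with a median of -0.018.

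Most genes of glycolysis and of the interferon response had small positive fold changes, as the pan T cell genes did, and none passed singly. Of 31 glycolysis and hypoxia genes, 28 had positive fold changes with a median of 0.12, and the list tested higher with an adjusted p of 9.06e-19 (limma cameraPR). Gapdh (0.15, SE 0.063), Ldha (0.14, SE 0.064), Pkm (0.13, SE 0.062) and Aldoa (0.16, SE 0.070), all enzymes of glycolysis, were among 5 genes at an unadjusted p under 0.05 in the authors' deposited table, while 0 passed over all genes and 0 adjusted over the list alone. Of 39 interferon response genes, 36 were positive with a median of 0.19 and an adjusted p of 3.11e-09 (limma cameraPR), although 0 passed by the authors' DESeq2 over all genes, at an unadjusted p under 0.05 or adjusted over the list alone. Examples in the authors' deposited table are Irf7 (0.29, SE 0.22), Ifi27l2a (0.26, SE 0.18) and Oas3 (0.19, SE 0.14). The 26 IL-6 and STAT3 response genes tested higher (adjusted p 0.00235, limma cameraPR), with 0 passing over all genes, 0 adjusted over the list alone, and Il4ra and Stat3 as the 2 at an unadjusted p under 0.05. That call was lost with a preset correlation of 0.1 (0.148) and after the GC trend was subtracted (0.0807), and with the fold change as statistic and without near-absent genes the list pointed lower, without passing (0.872). The 24 cholesterol biosynthesis genes, whose call was lost with a preset correlation of 0.05 (0.174) or a minimum mean of 50 (0.0992) and without near-absent genes (0.0547), had an adjusted p of 0.0484 in the higher direction (limma cameraPR), with 0 genes passing in any of these counts and Idi1 at -0.18 (SE 0.25) in the authors' deposited table.

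Ribosomal protein genes, 78 in number, also tested higher (median 0.067, adjusted p 1.29e-15, limma cameraPR), with 64 positive fold changes. Rpl39 (0.29, SE 0.096) and Rpl3 (0.14, SE 0.068) were among 3 at an unadjusted p under 0.05 in the authors' deposited table, with 0 passing over all genes and 0 adjusted over the list alone. Rps27rt, at -2.43 (SE 1.26) in the authors' deposited table, is a near-identical copy of another ribosomal protein gene, and its counts are uncertain.

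4 lists tested lower. The mitochondrially encoded list of 13 genes had a median of -0.43 and an adjusted p of 1.23e-37 (limma cameraPR), with 6 lower over all genes and 7 adjusted over the list alone, the seventh being mt-Nd6. Of the 7 that did not pass, 6 had a mean of 101 or less in the authors' deposited table, and since the mouse nuclear genome holds near-identical copies of part of the mitochondrial genome, their counts are uncertain. SR protein and nuclear speckle genes, many but not all of whose products bind pre-mRNA, had 28 of 32 fold changes below 0 (median -0.090, adjusted p 9.86e-05, limma cameraPR). Srsf1 was the 1 gene lower adjusted over the list alone, at -0.36 (SE 0.10) in the authors' deposited table, while 0 passed over all genes and Srsf2 (-0.25, SE 0.12) was the other at an unadjusted p under 0.05. Of 27 genes of the integrated stress and unfolded protein response, the chaperones Hspa5 (-0.36, SE 0.092), Hsp90b1 (-0.29, SE 0.088) and Calr (-0.24, SE 0.075) were lower adjusted over the list alone in the authors' deposited table, 0 passed over all genes, and the list had an adjusted p of 0.00283 (limma cameraPR), lost in the rank-based test (0.0935) and with a preset correlation of 0.1 (0.148). Of 19 heat shock and immediate early genes, 17 were below 0 (median -0.15, adjusted p 0.00915, limma cameraPR), with 0 passing over all genes, at an unadjusted p under 0.05 or adjusted over the list alone. Hspa1b stood at -0.54 (SE 0.33) in the authors' deposited table. That list lost its call with a preset correlation of 0.05 (0.0560) and the SR protein list with 0.1 (0.0869). With the fold change as statistic the SR protein, stress and heat shock lists pointed higher, without passing (0.785, 0.747 and 0.901). With near-absent genes also left out, these lists pointed lower again, without passing (0.706, 0.815 and 0.680, limma cameraPR).

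**Figure D3:**
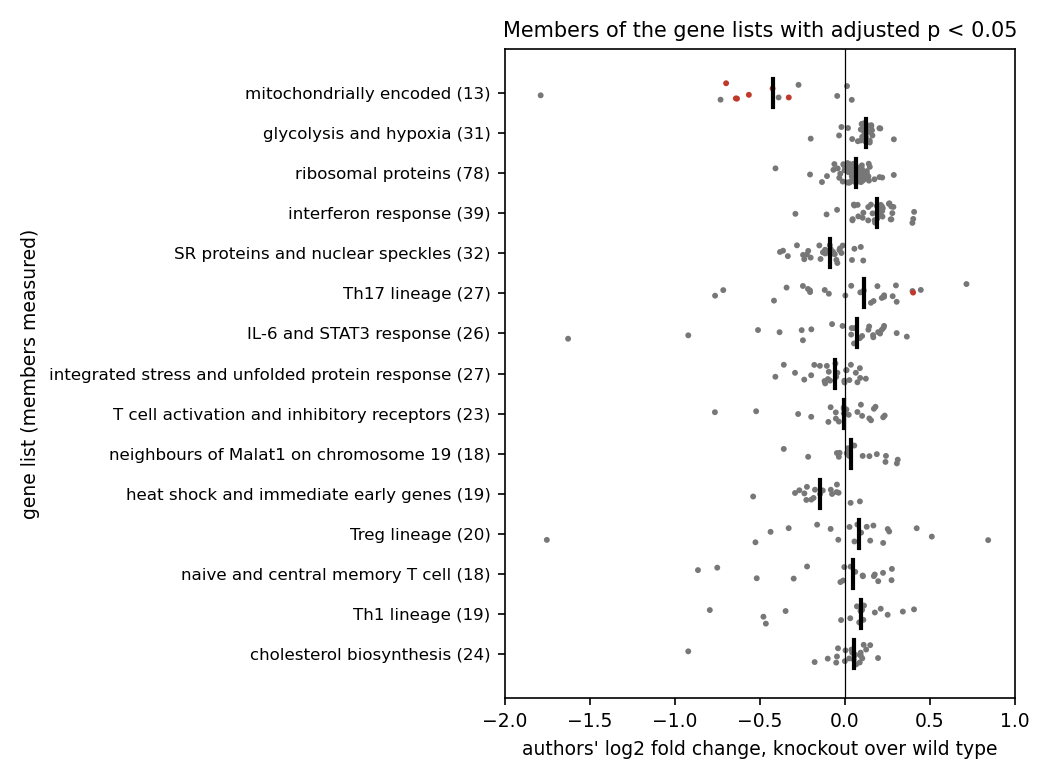
Log2 fold changes, knockout over wild type, of the measured members of the 15 lists with an adjusted p under 0.05 (limma cameraPR), 1 point per gene, red where the gene passed an adjusted p of 0.05 in the authors' deposited table, with a bar at each list's median and 1 point beyond the axis. Medians ran from -0.43 in the mitochondrially encoded list to 0.19 in the interferon response list.

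TGF-β signalling (27 genes, adjusted p 0.579), oxidative phosphorylation encoded in the nucleus (54, 0.512), S phase (40, 0.202), G2 and M phase (40, 0.597), replication-dependent histones (6, 0.627) and p53 and apoptosis (21, 0.141) did not pass (limma cameraPR). Their genes gave 0 over all genes by the authors' DESeq2 and 0 adjusted over the list alone. At an unadjusted p under 0.05 they gave 0 apart from Ltbp1 and Smad6 of the TGF-β list, both lower and with 3 and 1 counts in the knockout libraries. Ndufab1 (-0.28, SE 0.24), Ccne2 (-0.32, SE 0.36), Ccna2 (-0.16, SE 0.20), Bcl2l11 (0.30, SE 0.31) and Cdkn1a (0.14, SE 0.074) are examples from the authors' deposited table. The histone genes had a median knockout level of 0.484 normalized counts. None of the short structured RNAs was measured.

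Markers of other cell types were scarce in the knockout libraries. Median normalized counts were 0.967 for 11 B cell genes, 1.11 for 20 myeloid genes, 0.569 for 10 erythroid and platelet genes and 1.90 for 13 NK and gamma-delta T cell genes. C1qa and Blnk had 0 counts, whereas Ebf1, a B cell transcription factor, stood at 1137 ± 64.6 and Klrc1 at 913 ± 55.3 (SD, n = 2). Among 14 dendritic cell and MHC class II genes, H2-Ab1 stood at 1967 ± 266 while its partner chain H2-Aa stood at 4.38 ± 3.46 (SD, n = 2). Of the CD8 genes, Cd8b1 stood at 280 ± 8.21 and Cd8a at 4.42 ± 1.96 (SD, n = 2). By the authors' DESeq2, 0 of these genes passed over all genes and 0 adjusted over the list alone, and H2-Aa, lower in knockout, was the 1 at an unadjusted p under 0.05. The list tests gave adjusted p of 0.693 for B cell, 0.751 for myeloid, 0.438 for erythroid and platelet, 0.407 for NK and gamma-delta and 0.751 for dendritic cell genes (limma cameraPR). All 4 measured sex-linked genes were expressed, with 0 passing over all genes or adjusted over the list alone and 1 lower at an unadjusted p under 0.05.

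A knockout allele can alter its neighbours, so genes around Malat1 (chromosome 19, 5795690 to 5802672, GRCm38) were examined. Within 1 Mb, 0 of 90 genes passed by the authors' DESeq2, against 1 of 486 genes elsewhere on the chromosome, the near-absent Acy3 (two-sided Fisher's exact p = 1). At an unadjusted p under 0.05 there were 0 within 1 Mb and 16 elsewhere, and 5 within 5 Mb and 11 elsewhere. Within 5 Mb, Acy3 was the 1 of 238 genes that passed, against 0 of 338 (two-sided Fisher's exact p = 0.413). With 1 such gene on the chromosome the smallest p these tests allow is 0.156 and 0.413, so neither could show an effect on neighbours. The 18 measured genes of the fixed list of neighbours had a median of 0.034 and tested higher (adjusted p 0.00882, limma cameraPR), with 0 passing over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Frmd8 (0.31, SE 0.16), Ehbp1l1 (0.24, SE 0.15) and Capn1 (0.19, SE 0.14) are examples from the authors' deposited table. With the GC trend subtracted the adjusted p of this list was 0.0842 and its median -0.015, and with preset correlations of 0.05 and 0.1 the adjusted p was 0.0534 and 0.148.

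Fold changes followed GC content in the same way as the difference between the knockout libraries did. Across 7005 genes with a knockout mean of 500 or more, the Spearman correlation with GC content was 0.380 for the authors' fold change and 0.360 for replicate 1 over replicate 2, where genes are not independent replicates. The median log2 fold change ran from -0.11 in genes with a GC content of up to 40% to 0.067 between 56% and 60%. The correlation of the fold change with transcript length was -0.030.

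**Figure D4:**
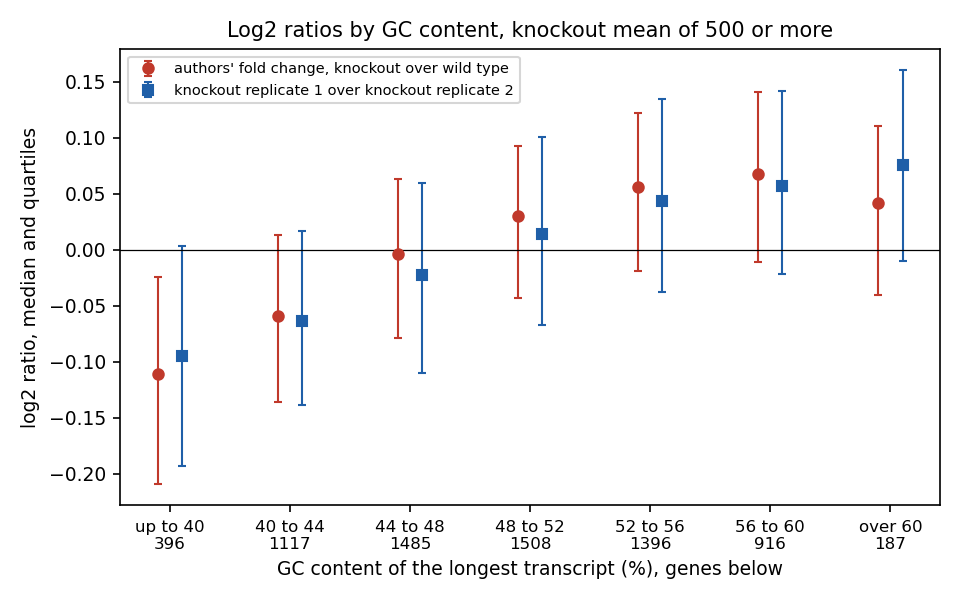
Median log2 ratio with quartiles (bars) by GC content of the longest transcript (percent, with the number of genes per bin), for genes with a knockout mean of 500 or more. Both the authors' fold change of knockout over wild type (red) and the ratio of knockout replicate 1 to replicate 2 (blue) lie below 0 up to 48% and above 0 from there.

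With preset correlations of 0.05 and 0.1 in place of 0.01, 8 and 4 of the 15 lists passed, and no correlation could be estimated. The 4 that passed at 0.1 were the mitochondrially encoded (adjusted p 2.62e-19), glycolysis and hypoxia (2.63e-06), ribosomal protein (0.00180) and interferon response lists (0.00584, limma cameraPR), and the other 11 lay between 0.0869 and 0.331. Once the GC trend was subtracted, the Th1 (0.0842), IL-6 and STAT3 (0.0807) and cholesterol lists (0.0807) no longer passed either. With the log2 fold change in place of the Wald statistic, in genes with a mean of 50 or more, 0 lists passed, the smallest adjusted p being 0.692, and 2 passed once near-absent genes were also left out.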

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

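Subtracting the GC trend and leaving out near-absent genes were settings chosen after the data were seen; the others were planned. The 23 genes with an adjusted p under 0.05 became 14 with a minimum change of 2-fold and 11 without the near-absent genes, and lay between 17 and 28 in the other settings. The count of higher genes was 0 with a minimum change of 1.5-fold, 0 with one of 2-fold and 2, Il17f and Itga3, at an adjusted p threshold of 0.1. The first 2 of these follow from the size of the Il17f change, and Itga3 was named after its values were seen. Of 15 gene lists, 8 passed with a preset correlation of 0.05 and 4 with 0.1, both of which widen the test by construction. With the log2 fold change as statistic 0 passed, and 2, the interferon and mitochondrially encoded lists, without near-absent genes; the cause was not tested. Directions reversed, all without passing, for SR proteins (adjusted p 0.785), heat shock (0.901) and the stress response (0.747) with that statistic (limma cameraPR). Without near-absent genes these 3 lists pointed lower again, without passing (0.706, 0.680 and 0.815), so their reversal depended on near-absent genes among the genes compared against. The direction of IL-6 and STAT3 (0.872) reversed with that statistic and without near-absent genes, and the cause was not tested. The rank-based test, the minimum mean of 50, the GC trend and the Wald statistic without near-absent genes left 10, 12, 11 and 14 of the 15 lists; the rank-based test lost the Th17, Treg, naive, activation and stress response lists. Scaling to genes other than the 20 most abundant moved the median ratio between the knockout libraries from 0.103 to 0.105. Leaving out each replicate in turn was not run, because the wild-type libraries are not among the samples analysed here. No paired analysis was possible because a replicate block needs those same libraries. The Bonferroni value of Malat1 was not run, since Malat1 is not analysed here. The authors' standard error had a median of 0.185 in 4862 genes with a mean of 1000 or more and 3.43 in 5407 genes with a mean under 50, none of them near-absent, so changes in the latter were hard to detect at this depth.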

Other observations

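All tests below were chosen after the result they bear on was seen, except those of 6 other tissue lists and of pan T cell genes.

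The near-absent genes, 0.637% of the implied wild-type total, include 20 of 25 kidney tubule genes (80%), led by Kap and Slc34a1 (implied wild-type means 11576 and 3254), and 15 of 25 mesenchymal and matrix genes, led by Sparc and Col1a1 (5956 and 5525), while Fn1, the most abundant of that list (14174), stands at 478 in knockout. RNA of kidney and mesenchymal cells in the wild-type libraries is thus a candidate source, although 2 and 6 of these members are among the 12 largest near-absent genes that prompted the lists, the knockout libraries express 1 and 4 list genes at 50 or more, and the isolation of naive CD4+ T cells would remove such cells. RNA of many tissues is argued against, since 3 of 149 genes of hepatocyte, neuron, muscle, intestine, lung and testis lists (2.01%) are near-absent, or 3 of the 95 measured (3.16%). In the 57 of 235 near-absent genes with 3 or more knockout counts, the authors' standard errors imply a median excess squared variation of 1.41, against 0.0365 in 10187 others. A wild-type library had been seen to stand apart before this test was chosen, so its outcome was known beforehand. No conclusion is drawn from it, and an even effect of Malat1 loss stays open in all 235. A replicate term in the authors' model may decide which of these genes passed: the 12 that did all had more counts in knockout replicate 2, against 49 of the 92 with a knockout count that did not pass (two-sided Fisher's exact p = 0.00122). Source and series cannot be told apart here, and either wild-type library alone may carry an implied mean, since that mean covers both and their own values, displayed before these tests were chosen, were not used.

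The 6 mitochondrially encoded transcripts that fell lay a median of -0.48 (log2) from the GC trend, whose median over them was -0.12. Among them, mt-Nd5, mt-Nd2, mt-Nd4 and mt-Nd1 lie where the trend is held flat. The distance argues against GC content as the whole cause only as far as that flat value holds. The 3 transcripts that lose the threshold once the trend is subtracted keep most of their fold changes (-0.58, -0.31 and -0.23). Foreign RNA in wild type cannot be told apart from a fall in knockout: the implied surplus of mitochondrial reads is 0.594 per implied read of the near-absent genes, and how much mitochondrial RNA a foreign cell type would bring is not known here. A share of mitochondrial RNA that varies between cultures of a genotype also stays open, since the knockout libraries differed in these genes by a median of 0.869 of the fall. An effect of Malat1 loss is untested beyond this, as genotype and series coincide.

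The rise of Il17f may reflect Malat1 loss, as a hypothesis. Subtracting the GC trend left it at 0.42 with an adjusted p of 0.000547, which argues against GC content. Dilution of T cell RNA in wild type by foreign RNA would raise all T cell genes alike, but the median of 18 pan T cell genes was 0.11 (range -0.12 to 0.23, 0 passing), 3.56 standard errors of Il17f below its fold change. The distance argues against dilution as the whole cause only. A part as large as the pan T cell median is not excluded. Whether Il17f would pass with that median subtracted was not tested. A difference between the series stays open, since no library here crosses genotype with series.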
